A study of Mus musculus with 8 samples.

How the data were processed

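The series holds 8 RNA-seq libraries of mouse CD4 T cells recovered after adoptive transfer into RAG-deficient hosts, 4 labelled as wild-type donors and 4 as Nlrp6 knock-out donors. Groups were taken from the labels' statement of the transferred cells, and the labels number the hosts 1, 2, 4 and 5 under each group. Per the labels' protocols, poly(A) RNA was made into libraries with a stranded TruSeq kit and read as single reads of 81 bases on a NextSeq 500. Per the labels, reads were aligned with STAR to mm10. The STAR version, the counting tool, its annotation and its strand setting are not given in the sources used here, so a gene and its antisense or overlapping partner cannot be told apart in these counts. The labels place the cells in the host spleen in one field and in the colonic lamina propria in others. The deposited values are raw counts per gene with Entrez identifiers, symbols and gene lengths, as their whole numbers and differing totals show. Each of the 11354 genes had about 1 CPM or more in at least 4 libraries (the lowest fourth-highest CPM was 0.987), so genes of low count had been left out before. No column of per-sample values was left unused. According to the design text, cells of both genotypes were transferred in equal numbers. Whether a host number stands for 1 mouse that received both kinds of cells is not stated in the labels, so the p-values measure the spread between these libraries.

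Totals ranged from 35198192 to 40310721 counts per library. Intervals on counts use counts summed over a label's libraries, so they cover counting error only and leave out the spread between libraries. The reads carry no molecular identifiers. Of the 11354 genes, 11337 were matched by Entrez identifier to the RefSeq gene table of GRCm38, the assembly that mm10 names, which gave positions and gene types, and 6 genes had no symbol. Counts were normalised with edgeR's TMM factors, and CPM were computed on those effective library sizes. filterByExpr on the groups kept all 11354 genes. Log2 CPM, used for principal components and for the myeloid level, had a prior count of 2. Genes were tested in edgeR with estimateDisp, glmQLFit and glmQLFTest on a model with the group alone, and Benjamini-Hochberg adjusted p below 0.05 made a call. The common biological coefficient of variation was 0.116. A gene's standard error is the absolute log2 fold change divided by the square root of the quasi-likelihood F. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

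Before the data were examined, 39 gene lists were fixed for T cell identity and programmes, pathways, RNA quality, other cell types, sex and the surroundings of Nlrp6. The 35 lists with at least 5 measured members were tested with camera on the edgeR fit with a preset inter-gene correlation of 0.01, adjusted over the 35 lists. The lists of B and plasma cells and of mitochondrial transcripts had 0 measured members and were not analysed here, and the CD8 and red cell lists, with 2 members each, were described without a list test. Counts called "adjusted over the list alone" apply Benjamini-Hochberg adjustment within a list. camera ranks a list against all other genes, whereas fry asks whether its genes move, on balance, in 1 direction. List results given for other settings also used camera with the preset correlation, unless fry or an estimated correlation is named. Summed CPM of markers of other cells and shares of counts were compared by two-sided exact permutation tests over the 70 assignments of 4 and 4 libraries, whose smallest p is 0.0286, with adjustment over the 8 lists or the 3 shares. Called genes per chromosome were compared by Fisher's exact test over 20 chromosomes and the 11332 genes placed on them, and the permutations of neighbouring calls and of blocks of genes used 10000 shuffles each, the latter adjusted over chromosomes by the largest standardised excess.

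The genes named were fixed by a rule written at the same time. They are Nlrp6, the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 1 and 1 direction in all 4 differences between same-numbered libraries, and the 4 members of each list with the smallest p. A set of T cell genes was always included, of which Il4 and Il18 were not analysed here. Members past the test when adjusted over their list alone could be added. Some genes that the rule names are not reported here. Unnamed gene models, pseudogenes and variable segments of antigen receptors were left out of the largest changes and counted. St6galnac1, St6galnac2, Camk2b and AA465934 fall outside the rule and were named after their values were seen. Alternatives fixed at that time were RLE size factors, total library size, no filter, a filter of 1 CPM in 4 libraries, limma-voom with quality weights, DESeq2, the host number as a block (also with RLE or DESeq2), the library code of the sample descriptions as a term, each library left out in turn, an adjusted p below 0.1, a log2 fold change of at least 1, an estimated inter-gene correlation and fry. Chosen after seeing the data were the myeloid level as a covariate (mean log2 CPM of the 20 genes of the myeloid list), the removal of the genes of chromosome 11 and the removal of KO 2 and KO 4.

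The tests were run on simulated counts for the 11354 genes, with means and library sizes of the real libraries and a known set of changed genes. For the comparison of the labels edgeR recovered 73.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, and 5.37% of its calls were unchanged genes. DESeq2 recovered 80.6%, 95.5% and 100% with 15.5% of calls unchanged, and limma-voom 73.1%, 91.0% and 100% with 5.39%. All recovered genes had the right sign. Of 50 unchanged simulated lists camera called 0. The simulated genes were drawn independently, so this does not test lists whose members move together, such as the myeloid list (estimated correlation 0.841). For chromosome 11, Fisher's test passed in 7 of 100 random placements of calls over 11332 genes and in 100 of 100 placements at double the rate. As a check for repeated files, the chi-square per degree of freedom between libraries of 1 label was 13.5 to 43.3, so no library repeated another at the level of counting noise.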

Results

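Poly(A) RNA was sequenced from CD4 T cells that had been transferred into RAG-deficient mice, hosts that make no T or B cells of their own. The labels give the donor cells as wild type in 4 libraries and as Nlrp6 knock-out in 4 libraries, with hosts numbered 1, 2, 4 and 5 under each label. The libraries are named WT 1, WT 2, WT 4 and WT 5 and KO 1, KO 2, KO 4 and KO 5 after their label and host. The source labels place the cells in the host spleen, whereas the extraction protocol and the design text place them in the colonic lamina propria, and the tissue is left open here. The table held whole-number counts for 11354 genes. Counts summed to 40310721 in WT 1, 39498477 in WT 2, 39157406 in WT 4 and 38003997 in WT 5. They summed to 38757841 in KO 1, 39325381 in KO 2, 35198192 in KO 4 and 39213031 in KO 5. Gene levels are given as CPM, counts scaled to library size, as mean ± SD over the 4 libraries of a label. Log2 fold changes are those of the libraries labelled knock-out over those labelled wild type, as value ± SE, positive where the libraries labelled knock-out were higher.

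Nlrp6, the gene the labels are about, encodes a NOD-like receptor that can assemble an inflammasome, and it lies on chromosome 7 from 140920902 to 140929192 (GRCm38). Its level went against the labels: the libraries labelled knock-out held 487, 329, 477 and 648 Nlrp6 counts for hosts 1, 2, 4 and 5, and the libraries labelled wild type held 5, 3, 3 and 8. This was 0.121 ± 0.0625 CPM under the wild-type label and 12.8 ± 3.34 CPM under the knock-out label (SD, n = 4 each). The summed counts were 19 and 1941, a ratio of 105 per total count with a 95% exact interval of 67.2 to 175 that covers counting error only. In edgeR's quasi-likelihood test the log2 fold change was 6.70 ± 0.32 with adjusted p = 4.07e-06. A two-sided exact permutation test of the CPM gave p = 0.0286, the smallest that the 70 assignments of 4 and 4 libraries allow. The counts are per gene and the labels do not describe the targeted allele, so reads from an intact gene and reads from what a targeted allele still transcribes are counted alike. Because of this gene, every direction given here is that of libraries labelled knock-out or labelled wild type, not of a genotype.

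The comparison of the labels addresses which transcripts differ between transferred CD4 T cells with and without Nlrp6. Libraries labelled knock-out held more of the transcripts known from macrophages, monocytes and antigen-presenting cells, such as Csf1r at 4.38 ± 1.25 CPM under the wild-type label and 67.7 ± 31.6 CPM under the knock-out label. They also held more of several genes on chromosome 11, led by the long non-coding RNA BC018473. Il10, an anti-inflammatory cytokine, was at 93.7 ± 28.2 CPM under the wild-type label and 16.8 ± 16.1 CPM under the knock-out label, and Il21, Cxcr5 and the protease Ctse were lower as well. The memory-associated genes Tcf7, Il7r and Ccr7 were higher, whereas Ifng, Tbx21, Foxp3 and Mki67 did not pass the test. Ccr7, which dendritic cells also carry, and Il7r lost their calls without KO 2 and KO 4 (edgeR adjusted p = 0.0576 and 0.131). In all, edgeR's quasi-likelihood test called 1140 of 11354 genes (10.04%) at an adjusted p below 0.05, 704 higher and 436 lower in the libraries labelled knock-out. Of these, 380 were at least 2-fold higher and 68 at least 2-fold lower, and the median absolute log2 fold change was 0.70. The labels' libraries did not overlap in CPM for 1090 of the called genes and for 1813 of all genes (16.0%), where chance gives 2.86%. The first principal component of log2 CPM carried 71.3% of the variance and separated the labels, from -37.8 to -24.8 for the libraries labelled wild type and from 19.6 to 40.8 for those labelled knock-out. With the mean myeloid level of each library as a covariate, chosen after seeing the data, 7 of the 1140 calls remained, because the fold changes of the higher genes shrank (median log2 1.18 to 0.28) while the standard errors grew (median 0.214 to 0.462 for the higher genes and 0.0846 to 0.281 for the lower ones). With the library code of the submitters' sample descriptions as a term (8 for KO 4 and KO 5, 7 for the others) 688 of the 1140 calls remained. That fit takes the label difference from KO 1 and KO 2 alone against the libraries labelled wild type. The 436 lower genes became 277 without WT 1 and 276 without KO 1.

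The 12 largest rises among named genes were led by BC018473, ahead of Nlrp6. BC018473 is a long non-coding RNA on chromosome 11 from 116752167 to 116757883. It was at 0.541 ± 0.264 CPM under the wild-type label and 736 ± 30.4 CPM under the knock-out label (SD, n = 4 each), a log2 fold change of 10.41 ± 0.18 (edgeR adjusted p = 3.45e-09). St6galnac1 and St6galnac2, sialyltransferase genes on either side of it that were singled out after their values were seen, rose by 3.69 ± 0.21 and 3.87 ± 0.09. Mxra7, on chromosome 11 from 116803400 to 116828127, rose by 4.26 ± 0.26, from 0.303 ± 0.0601 to 5.89 ± 1.45 CPM. The other large rises included receptors known from myeloid and natural killer cells. Sirpb1a (chromosome 3, 15371661 to 15426522) rose by 4.66 ± 0.43, and Klra2, a C-type lectin receptor gene (chromosome 6, 131198970 to 131247716), by 4.26 ± 0.38. The Fc receptor genes Fcgr1 (chromosome 3, 96282909 to 96293969) and Fcgr4 (chromosome 1, 171018926 to 171029761) rose by 4.17 ± 0.50 and 4.11 ± 0.36, the latter from 1.00 ± 0.180 to 17.4 ± 8.12 CPM. Clec4a3 (4.16), Gpr141 (4.13), the complement receptor C3ar1 (4.13), Pira6 (4.24) and the X-linked Xlr3c (4.43) completed the set, with edgeR adjusted p-values of at most 0.00100 over all 12. Sirpb1a, Klra2, Pira6, Xlr3c and Clec4a3 have close relatives in the genome, so their counts are uncertain where reads were shared. The myeloid level described with the marker lists differed by 2.90 log2 units between the same libraries. With it as a covariate 2 of the 12, Nlrp6 and BC018473, stayed called, Mxra7 (5.03) and Xlr3c (5.45) were higher than without it and did not pass, and the others were lower and did not pass.

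The largest falls included genes with T cell, protease and adhesion functions. Krt17, a keratin gene on chromosome 11 from 100256215 to 100261029, fell from 5.35 ± 2.93 to 0.0829 ± 0.0731 CPM (-5.92 ± 0.64, edgeR adjusted p = 0.000488, and -6.57 without KO 2). Itgad, an integrin alpha chain gene (chromosome 7, 128173933 to 128205504), fell from 27.5 ± 4.29 to 1.04 ± 0.348 CPM (-4.71 ± 0.21, adjusted p = 2.48e-06). Rgs10, a regulator of G-protein signalling that lies close to Itgad (chromosome 7, 128373621 to 128419506), fell from 58.9 ± 7.85 to 7.13 ± 0.864 CPM (-3.05 ± 0.12, adjusted p = 1.16e-06). Ctse, the gene of the aspartic protease cathepsin E (chromosome 1, 131638314 to 131675507), fell from 322 ± 25.04 to 68.3 ± 6.14 CPM (-2.24 ± 0.08, adjusted p = 5.00e-07). Il10 lies on the same chromosome (chromosome 1, 131019845 to 131024970) and fell by 2.49 on the log2 scale (SE 0.53, adjusted p = 0.0158), with 40.8 CPM in KO 4 and 6.34 to 10.3 CPM in the other libraries labelled knock-out. Without KO 4 its log2 fold change was -3.41. Log2 fold changes of the others were -3.75 for Serpina9, -3.28 for BC147527, -2.89 for Ptpn5, -2.22 for Tmem132e, -2.14 for Bace2, -2.12 for Il9r and -2.03 for Mpp7, with edgeR adjusted p-values of at most 0.00834. Ptpn5 was at 3.18 CPM in KO 2, and without KO 2 its log2 fold change was -3.68. BC147527 has close relatives, and its count is uncertain for that reason. All 24 genes kept their calls in each of the 8 fits that left out 1 library. The rule behind these names was met by 567 genes that rose and 392 that fell, and by a further 18 and 12 unnamed models, pseudogenes or receptor segments.

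**Figure D1:**
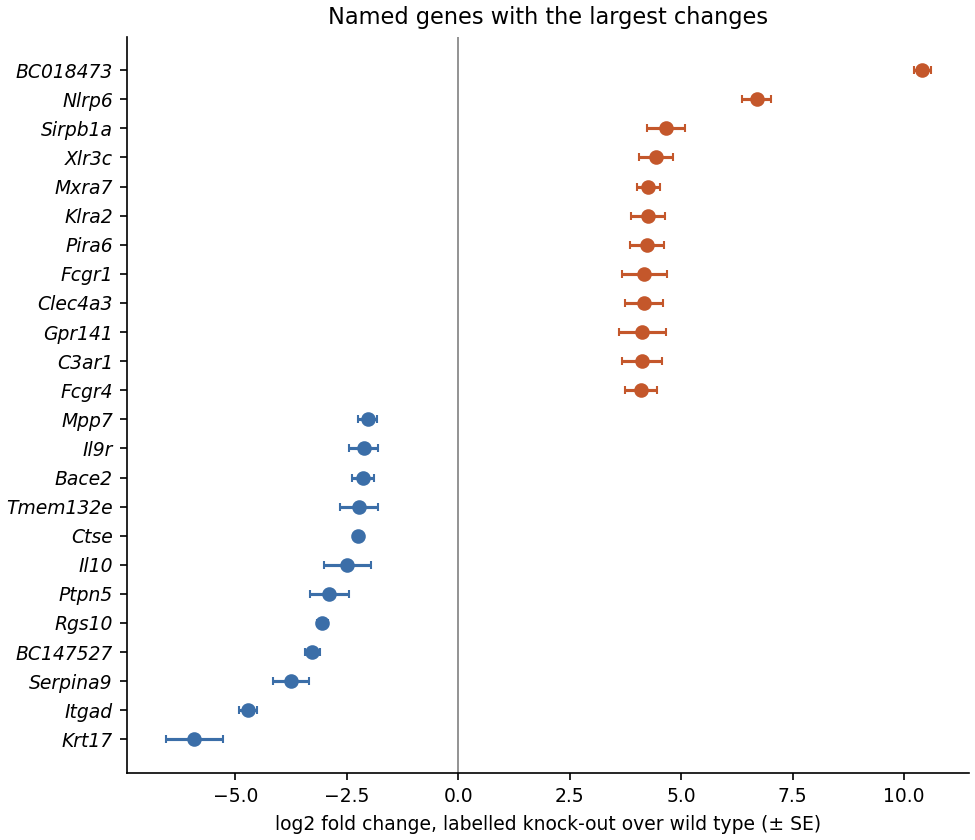
Log2 fold changes (x axis, libraries labelled knock-out over wild type, bars show SE, n = 4 libraries per label) of the 12 largest rises, Nlrp6 among them, and the 12 largest falls among named genes that passed edgeR's test. BC018473 stands apart at 10.41, Nlrp6 lies at 6.70, the other rises lie between 4.11 and 4.66, and the falls reach from -2.03 to -5.92.

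Markers of myeloid cells rose together in the libraries labelled knock-out. Of the 20 genes in the myeloid list, 18 rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 3.41. The growth factor receptor Csf1r rose by 3.95 ± 0.39, the macrophage marker Adgre1 by 3.81 ± 0.41, the complement gene C1qb by 3.50 ± 0.38 and the Fc receptor gene Fcgr3 by 3.36 ± 0.34 (edgeR adjusted p at most 0.000488). Summed over the list, their level was 193 ± 25.7 and 917 ± 361 CPM under the wild-type and knock-out labels (SD, n = 4 each, ratio 4.76). Every library labelled knock-out lay above every library labelled wild type (two-sided exact permutation p = 0.0286, adjusted over the 8 lists of other cells p = 0.0762). At this smallest possible p, the adjusted value depends on the p-values of the other lists and not on the size of the difference. The mean log2 CPM of the myeloid list was 1.78 ± 0.399 and 4.68 ± 0.638, a difference of 2.90. In the list of dendritic cell and MHC class II genes, 8 of 11 rose and 0 fell (9 and 0 adjusted over the list alone), among them Cd74 (3.12 ± 0.29), H2-Eb1 (3.71 ± 0.36), H2-Aa (3.62 ± 0.35) and Sirpa (3.56 ± 0.34). In the neutrophil list, 8 of 12 rose and 0 fell (11 and 0 adjusted over the list alone), including the receptors Csf3r (3.12), Trem1 (3.28) and Clec4d (2.70), the chemokine Cxcl2 (2.97) and the calprotectin genes S100a8 (1.87) and S100a9 (1.36). With the myeloid covariate Cxcl2 (-0.0326) and S100a9 (-0.19) turned downward and did not pass. With 1 library left out at a time, the call of S100a9 held in 1 of 8 fits, and its highest adjusted p was 0.125 without WT 4. The call of S100a9 ended with the library code as a term (adjusted p = 0.315).

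Summed dendritic and MHC class II levels were 126 ± 26.1 and 948 ± 380.0 CPM under the wild-type and knock-out labels, and neutrophil levels were 151 ± 23.2 and 232 ± 70.2 CPM (exact permutation p = 0.0286 and adjusted p = 0.0762 for each). camera with a preset correlation called the myeloid (1.99e-35), dendritic (2.23e-15) and neutrophil (5.07e-11) lists by adjusted p, and these calls were lost at adjusted p = 0.212, 0.212 and 0.235 with an estimated correlation. In the list for natural killer and innate lymphoid cells, 2 of 8 rose and 0 fell (3 and 0 adjusted over the list alone). Its risers Fcer1g (3.65 ± 0.37) and Tyrobp (3.35 ± 0.41) are signalling adaptors that myeloid cells also express, and Tyrobp turned downward with the myeloid covariate (-0.27) and did not pass. Kit (0.91) and Klrb1b (-0.41) did not pass. Kit passed without KO 2 (1.13, adjusted p = 0.0180). The list's camera adjusted p was 0.0413, or adjusted p = 0.541 with an estimated correlation. The call was also lost with limma-voom (0.145) and without WT 2 (0.0752), WT 4 (0.0695) or WT 5 (0.0678). The host number as a block ended it too (0.0603, or 0.0590 with RLE factors), and the list turned downward with the myeloid covariate (0.903). The list's summed level was 331 ± 58.6 and 382 ± 38.1 CPM under the wild-type and knock-out labels (exact permutation p = 0.20). Of the CD8 pair, Cd8a rose by 2.21 ± 0.53 (edgeR adjusted p = 0.0280), from 4.10 ± 1.71 to 19.0 ± 14.7 CPM, while Cd8b1 was at 2.39 ± 1.43 CPM under the wild-type label and 1.95 ± 0.893 CPM under the knock-out label (-0.29 ± 0.48). Without KO 2 the log2 fold change of Cd8a was 1.57. The call of Cd8a held in 4 of the 8 fits that left out 1 library, and its highest adjusted p was 0.0876 without WT 4. The summed CD8 level was 6.49 ± 2.54 and 21.0 ± 15.3 CPM (exact permutation p = 0.0571).

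Markers of epithelium, stroma and red cells showed no rise of that size. Of 5 epithelial genes 0 rose and 0 fell, and their summed level was 35.5 ± 6.31 and 36.4 ± 2.31 CPM under the wild-type and knock-out labels (exact permutation p = 0.857). Lgals4 (-0.23), Cdh17 (0.65), Cdh1 (0.77) and Krt18 (-0.32) differed by less than the test could call, and Cdh1 passed without WT 5 (log2 fold change 1.37, adjusted p = 0.00510). Lgals4 passed without WT 2 (-0.32, adjusted p = 0.0497). Of 17 stromal and endothelial genes 0 rose and 0 fell, at a summed 2692 ± 192 and 2844 ± 165 CPM (exact permutation p = 0.257). That sum includes Thy1, also a member of the T cell identity list, so it does not measure stromal cells alone. The endothelial genes Kdr (1.04), Pecam1 (0.31), Cdh5 (0.69) and Plvap (0.72) did not pass in edgeR's test (adjusted p from 0.0847 to 0.195), although Kdr passed without WT 5 (1.44, adjusted p = 0.0106). Without KO 4, Kdr (1.19, adjusted p = 0.0483), Cdh5 (0.90, adjusted p = 0.0373) and Plvap (0.94, adjusted p = 0.0302) passed. The globin genes Hbb-bs (-0.35) and Hba-a2 (-0.04), the red cell genes measured, did not pass, at a summed 19.2 ± 5.17 and 17.3 ± 4.59 CPM (exact permutation p = 0.571). Adjusted over the list alone, edgeR also called 0 of these genes, and at an unadjusted p under 0.05 it called 1 epithelial gene (lower), 5 stromal genes (all higher) and 0 red cell genes. DESeq2 and limma-voom each called 1 stromal gene, higher, and 0 epithelial or red cell genes. The camera adjusted p-values of the epithelial and stromal lists were 0.899 and 0.436, and the stromal list passed, upward, with limma-voom (0.0476), with the myeloid covariate (0.0393) and without KO 2 and KO 4 (0.00530). With the estimated correlation of 0.652 camera gave the stromal list adjusted p = 0.936 with all libraries.

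**Figure D2:**
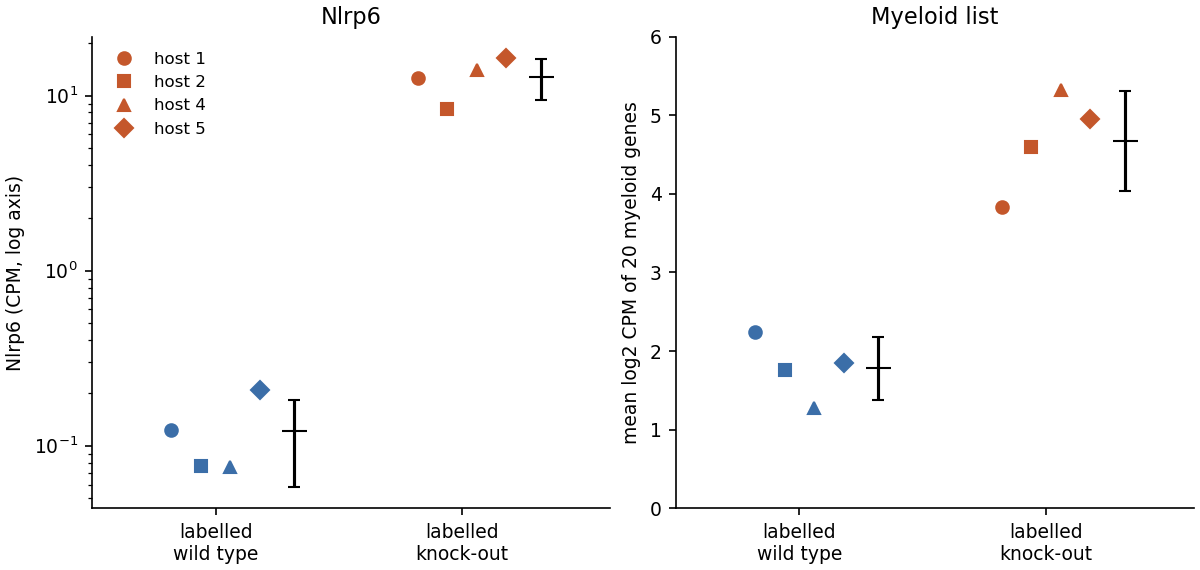
Nlrp6 (left, CPM on a log axis) and the mean log2 CPM of the 20 genes of the myeloid list (right) in each library, with symbols for the host number and a bar for the mean ± SD of each label (n = 4). Nlrp6 lay between 0.0759 and 0.209 CPM in the libraries labelled wild type and between 8.38 and 16.3 CPM in those labelled knock-out, and the myeloid means were 1.78 and 4.68.

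Genes of helper T cell programmes moved in both directions. Among follicular helper genes, 2 of 11 fell and 1 rose (6 and 2 adjusted over the list alone). The follicle homing receptor Cxcr5 fell from 45.6 ± 16.4 to 13.8 ± 4.27 CPM (-1.73 ± 0.27, edgeR adjusted p = 0.00316) and the receptor Slamf6 from 98.8 ± 12.9 to 65.4 ± 8.18 CPM (-0.60 ± 0.11, adjusted p = 0.00674). The riser was Cebpa (2.16 ± 0.35), a transcription factor best known from myeloid cells, at 0.508 ± 0.104 CPM under the wild-type label and 2.29 ± 0.977 CPM under the knock-out label. Bcl6, the lineage regulator, did not pass (0.30 ± 0.09, adjusted p = 0.0588) but did without WT 2 (0.35, adjusted p = 0.0476). In the regulatory T cell list of 18 genes, Il10 and the costimulatory receptor Tnfrsf4 (-0.59 ± 0.10) fell and the ectonucleotidase Nt5e rose (0.31 ± 0.07), against 3 and 1 adjusted over the list alone. Foxp3 was at 5.94 ± 4.18 CPM under the wild-type label and 3.34 ± 1.73 CPM under the knock-out label (-0.83 ± 0.49, adjusted p = 0.364). Its log2 fold change lay between -1.23 (without KO 4, adjusted p = 0.165) and -0.235 with 1 library left out, and passed in 0 of those 8 fits. Tnfrsf18 (-0.39) passed without KO 4 (-0.49, adjusted p = 0.0130). In the Th17 list of 20 genes, the cytokine Il21 fell from 121 ± 26.4 to 48.0 ± 8.35 CPM (-1.33 ± 0.17, adjusted p = 0.000997), the transcription factor Batf fell (-0.31 ± 0.07) and the cytokine receptor gene Il6ra rose (1.19 ± 0.33), also 2 and 1 adjusted over the list alone. With the myeloid covariate Il6ra (-1.61) and Cebpa (-0.53) turned downward and did not pass. In the 8 fits without 1 library each, the calls of Nt5e, Batf and Il6ra held in 4, 7 and 1, and the highest adjusted p-values were 0.0832 without WT 1, 0.0578 without WT 1 and 0.126 without WT 2. The calls of Batf and Il6ra ended with the library code as a term (adjusted p = 0.114 and 0.317). Without KO 2 and KO 4 the calls of Slamf6, Nt5e, Batf and Il6ra were lost (edgeR adjusted p = 0.0502, 0.0601, 0.0972 and 0.166).

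Il17a was at 0.07 ± 0.52, or -0.73 without KO 5, and did not pass in either fit. Maf, a transcription factor that drives Il10, was at -0.78 ± 0.27 (edgeR adjusted p = 0.119), or -1.16, adjusted p = 0.000815 without KO 4. In the Th2 list of 7 genes, the chemokine receptor Ccr8 (-0.64 ± 0.14) and the zinc finger gene Gfi1 (-0.27 ± 0.05) fell and 0 rose (2 and 1 adjusted over the list alone), whereas Il4ra (0.41), Areg (0.50) and the regulator Gata3 (0.03) did not pass. Among fits without 1 of the 8 libraries, 6 kept the call of Ccr8, and its highest adjusted p was 0.0584 without WT 1. The call of Ccr8 ended with the library code as a term (adjusted p = 0.0619). In the Th1 list, 1 of 20 genes rose and 0 fell, also adjusted over the list alone. It was Ly6c2, a surface antigen of effector T cells and monocytes, which went from 12.1 ± 3.35 to 30.4 ± 5.88 CPM (1.33 ± 0.19, adjusted p = 0.00204). Ifng was at 817 ± 40.02 CPM under the wild-type label and 853 ± 191 CPM under the knock-out label (0.06 ± 0.13), Tbx21 at -0.01 ± 0.09, Il18rap at 0.26 ± 0.09, Cxcr3 at -0.24 ± 0.09 and Il2 at 0.78 ± 0.31, and Il18rap passed without WT 5 (0.35, adjusted p = 0.0204). With all libraries none of these 4 lists passed camera, at adjusted p = 0.180 for follicular helper, 0.211 for regulatory, 0.501 for Th2 and 0.542 for Th1 genes. The regulatory list passed, downward, without KO 4 (0.00122), without KO 2 and KO 4 (0.00302) and with the myeloid covariate (3.40e-06), and the follicular list passed by fry (0.0376). These camera values use the preset correlation. With the estimated correlation of 0.277 camera gave the regulatory list adjusted p = 0.840 with all libraries. The Th17 list (adjusted p = 0.547) had a positive median (0.06) and mean (0.11) while camera ranked it downward, and the Th2 list had a median of 0.01 and a mean of -0.04. The median of the regulatory list was -0.23, and that of the follicular list -0.38. The myeloid level differed by 2.90 log2 units between the same libraries, beside all of these groups.

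**Figure D3:**
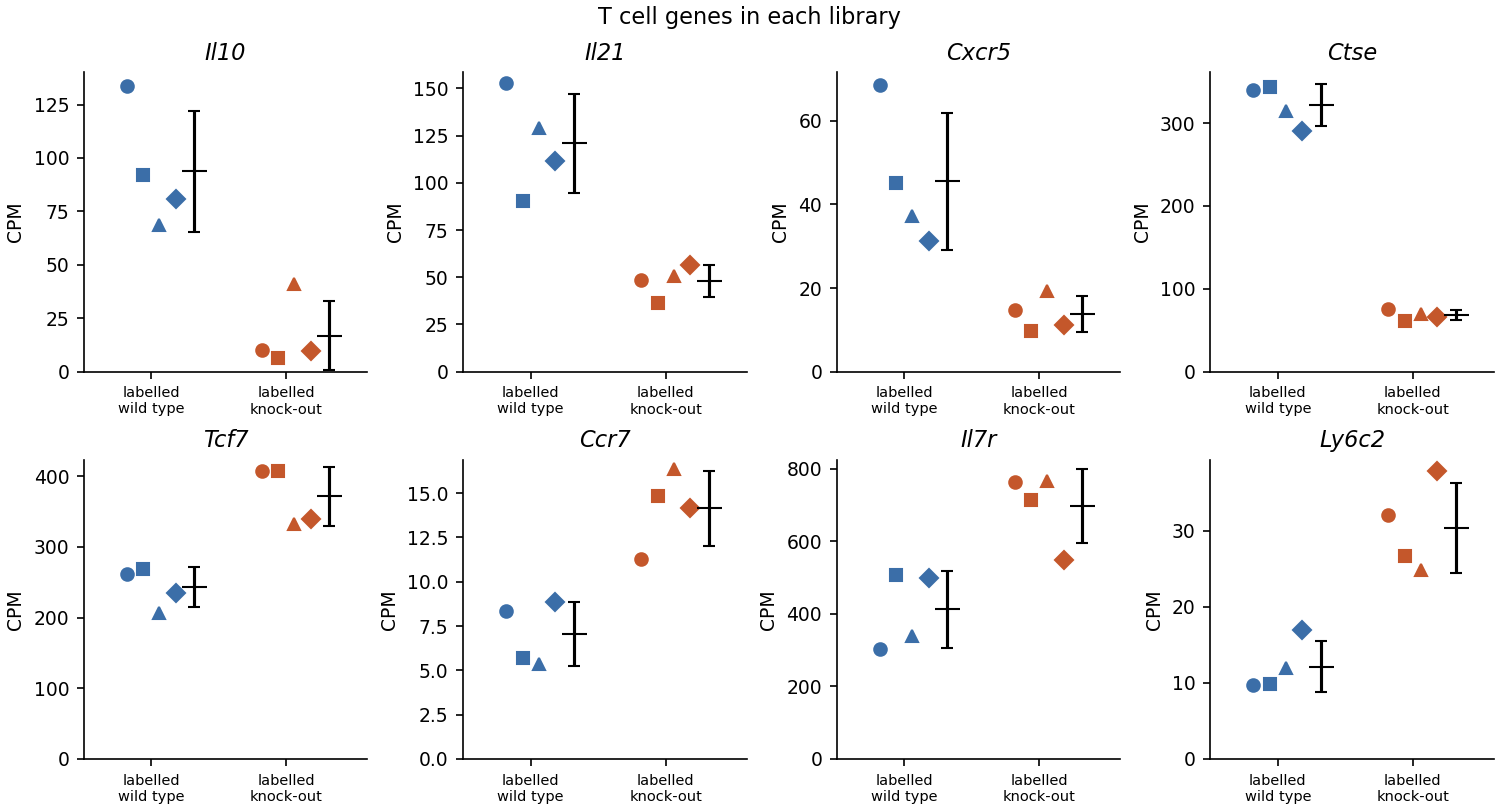
CPM (y axis) of 8 genes drawn as T cell genes in each library, with circles, squares, triangles and diamonds for hosts 1, 2, 4 and 5 and a bar for the mean ± SD of each label (n = 4). Ccr7 is also carried by dendritic cells and Ly6c2 by monocytes. Il10, Il21, Cxcr5 and Ctse were lower, and Tcf7, Ccr7, Il7r and Ly6c2 higher, in every library labelled knock-out than in any labelled wild type, with Il10 at 40.8 CPM in KO 4.

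Genes of naive and memory T cells rose in part, beside the myeloid difference of 2.90. In this list 5 of 15 rose and 0 fell (7 and 0 adjusted over the list alone), with a median log2 fold change of 0.29. Tcf7, a transcription factor of naive and memory cells, rose from 243 ± 28.4 to 372 ± 41.6 CPM (0.61 ± 0.10, edgeR adjusted p = 0.00350). The lymph node homing receptor Ccr7 rose from 7.05 ± 1.79 to 14.1 ± 2.12 CPM (1.00 ± 0.18), the cytokine receptor gene Il7r from 412 ± 106 to 698 ± 102 CPM (0.76 ± 0.18), Ly6c1 by 0.94 ± 0.16 and Klf3 by 0.47 ± 0.12. camera called the list at adjusted p = 0.0151, a call lost at adjusted p = 0.212 with an estimated correlation, 0.0649 without KO 1 and 0.0800 with the myeloid covariate. With that covariate Ccr7 (-0.25) and Klf3 (-0.30) turned downward and did not pass. With 1 library left out at a time, the calls of Il7r and Klf3 held in 4 and 2 of 8 fits, and the highest adjusted p-values were 0.0736 without WT 4 and 0.110 without WT 2. The calls of Il7r and Klf3 ended with the library code as a term (adjusted p = 0.0568 and 0.241). Without KO 2 and KO 4 the calls of Ccr7 and Il7r were lost (edgeR adjusted p = 0.0576 and 0.131). Ccr7 is also carried by dendritic cells and the Ly6c genes by monocytes, and Ly6c1 and Ly6c2 are near-copies that reads can be shared between. Of 16 genes of T cell identity, 3 fell and 0 rose (4 and 2 adjusted over the list alone), with a median of -0.10 and a camera adjusted p of 0.0905. That list passed, downward, with limma-voom (0.0123), without WT 5 (0.0158), without KO 4 (0.0165) and without KO 2 and KO 4 (0.00530). It also passed, downward, with the host number as a block (0.0369, or 0.0168 with DESeq2). With the estimated correlation of 0.272 camera gave it adjusted p = 0.788 with all libraries. The fallers were the signalling genes Zap70 (-0.27 ± 0.07) and Cd247 (-0.40 ± 0.11) and the costimulatory receptor Cd27 (-0.66 ± 0.17). The calls of Zap70, Cd247 and Cd27 held in 3, 2 and 2 of the 8 fits that left out 1 library, and their highest adjusted p-values were 0.0876, 0.118 and 0.0988 without KO 1. The calls of Zap70 and Cd27 ended with the library code as a term (adjusted p = 0.0695 and 0.0882). Cd4 was at 1446 ± 112 CPM under the wild-type label and 1222 ± 174 CPM under the knock-out label (-0.24 ± 0.10, adjusted p = 0.167) and passed without KO 4 (-0.35, adjusted p = 0.00963). Cd3e (-0.06), Cd2 (-0.27) and Ptprc (0.16) did not pass, and Cd2 did without WT 5 (-0.32, adjusted p = 0.0295) and without KO 4 (-0.31, adjusted p = 0.0412).

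Inhibitory, cytotoxic and homing receptors showed few calls beside the same myeloid difference of 2.90. Among 15 coinhibitory genes, the receptor Cd200r1 fell (-0.69 ± 0.13, edgeR adjusted p = 0.00927) and Cd244, which monocytes and natural killer cells also express, rose (2.28 ± 0.35, adjusted p = 0.00264), against 3 and 1 adjusted over the list alone. Lag3, an inhibitory receptor, was at 147 ± 44.4 CPM under the wild-type label and 60.8 ± 36.3 CPM under the knock-out label (-1.27 ± 0.36, adjusted p = 0.0570) and passed without KO 4 (-1.77, adjusted p = 0.00129), as did the transcription factor Prdm1 (-0.41 ± 0.13 with all libraries, -0.58, adjusted p = 0.000173 without KO 4). camera gave this list adjusted p = 0.176 at a median of -0.37 with all libraries. It passed, downward, without KO 4 (2.63e-05), without KO 2 and KO 4 (2.87e-06), with limma-voom (0.0123), with the library code as a term (0.0290) and with the myeloid covariate (6.85e-05). These values rest on the preset correlation of 0.01, where 0.201 was estimated for the list. With that estimate camera gave adjusted p = 0.788 with all libraries. Among 19 cytotoxic genes, the protease gene Ctsw (0.37 ± 0.08) and the granzyme inhibitor gene Serpinb9 (0.43 ± 0.11) rose and 0 fell, also adjusted over the list alone. Gzma (1.19 ± 0.39) and Ccl5 (-0.71 ± 0.24) did not pass, and passed without KO 2 (1.43, adjusted p = 0.0346) and without KO 4 (-0.99, adjusted p = 0.00490). Among 18 homing and adhesion genes, the oxysterol receptor Gpr183 (0.58 ± 0.12) and the retention marker Cd69 (0.31 ± 0.09) rose and the integrin chain Itgb2 fell (-0.20 ± 0.04), against 3 and 1 adjusted over the list alone. In the 8 fits without 1 library each, the calls of Ctsw, Serpinb9, Gpr183, Cd69 and Itgb2 held in 5, 3, 7, 2 and 7, and the highest adjusted p-values were 0.0597 without WT 4, 0.101 without KO 2, 0.0520 without WT 1, 0.130 without KO 1 and 0.0535 without KO 1. The calls of Cd200r1, Serpinb9, Itgb2 and Cd69 ended with the library code as a term (adjusted p = 0.0525, 0.131, 0.0552 and 0.177). Itga1 (0.75 ± 0.23) passed without WT 5 (1.07, adjusted p = 0.000603). The cytotoxic and homing lists had camera adjusted p-values of 0.830 and 0.411.

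In the list of inflammasome and NOD-like receptor genes, 4 of 21 rose and 1 fell (5 and 1 adjusted over the list alone). The cytokine gene Il1b rose from 13.7 ± 1.73 to 172 ± 89.2 CPM (3.64 ± 0.36, edgeR adjusted p = 0.000381), the sensor Nlrp3 from 2.86 ± 0.524 to 28.7 ± 14.8 CPM (3.32 ± 0.37) and the pyrin gene Mefv from 0.660 ± 0.198 to 7.47 ± 4.54 CPM (3.49 ± 0.46), and all of these are known to be abundant in myeloid cells, whose level differed by 2.90. The kinase gene Ripk2 rose by 0.27 ± 0.07. The adaptor gene Pycard, which links sensors to caspase, fell from 55.9 ± 3.36 to 42.0 ± 5.07 CPM (-0.41 ± 0.09, adjusted p = 0.0137). That call was lost with the library code as a term (adjusted p = 0.0594) and without KO 2 and KO 4 (adjusted p = 0.0606). Casp1 was at 142 ± 12.9 CPM under the wild-type label and 131 ± 3.61 CPM under the knock-out label (-0.12 ± 0.06, adjusted p = 0.292). The list's median was 0.03, its mean 0.51 and its camera adjusted p 0.189. Il18 was not analysed here. Among fits without 1 of the 8 libraries, 3 kept the call of Ripk2, and its highest adjusted p was 0.0825 without KO 2. The call of Ripk2 ended with the library code as a term (adjusted p = 0.132). Among genes of the NF-kappa-B response, 11 of 25 rose and 0 fell (15 and 0 adjusted over the list alone). They included the kinase gene Map3k8 (0.50 ± 0.09), the surface antigen Cd83 (2.13 ± 0.41), Ier3 (1.21 ± 0.26), the inhibitor gene Nfkbia (0.27 ± 0.06) and Icam1 (0.41 ± 0.10), and Cd83 and Icam1 are also carried by antigen-presenting cells. camera called the list at adjusted p = 7.68e-05, and the call was lost at adjusted p = 0.427 with an estimated correlation and 0.570 with the myeloid covariate. With that covariate Cd83 (-1.38), Ier3 (-0.74) and Mefv (-0.23) turned downward and did not pass. With 1 library left out at a time, the calls of Ier3, Nfkbia and Icam1 held in 7, 4 and 5 of 8 fits, and the highest adjusted p-values were 0.0548 without WT 4, 0.0710 without WT 4 and 0.0689 without WT 2. The calls of Cd83, Ier3, Nfkbia and Icam1 ended with the library code as a term (adjusted p = 0.0511, 0.0985, 0.149 and 0.154).

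Survival genes rose in part. Among 21 anti-apoptotic genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone): the kinase gene Pim1 (0.44 ± 0.09), Birc3 (0.27 ± 0.07), Traf1 (0.25 ± 0.07), the cytokine receptor chain Il2rg (0.23 ± 0.06) and Il7r. Bcl2 was at 50.9 ± 14.5 CPM under the wild-type label and 53.7 ± 14.7 CPM under the knock-out label (0.08 ± 0.23, edgeR adjusted p = 0.896). The calls of Birc3, Traf1 and Il2rg held in 3, 2 and 2 of the 8 fits that left out 1 library, and their highest adjusted p-values were 0.0867, 0.128 and 0.0962 without WT 1. The call of Traf1 ended with the library code as a term (adjusted p = 0.150). Among 31 pro-apoptotic genes, 1 fell and 1, the death receptor gene Tnfrsf10b, rose (0.62 ± 0.14), against 3 and 2 adjusted over the list alone. Bid (-0.37 ± 0.10) and Mlkl (0.54 ± 0.16) did not pass, and Bid did without KO 4 (-0.45, adjusted p = 0.0145). Of 21 p53 targets, 4 rose and 0 fell (5 and 1 adjusted over the list alone), namely Tnfrsf10b, the cell cycle inhibitor gene Cdkn1a (0.50 ± 0.10) and the sestrin genes Sesn1 (0.49 ± 0.12) and Sesn2 (0.32 ± 0.06). With the myeloid covariate Cdkn1a (-0.19) and Sesn1 (-0.38) turned downward, and none of the 4 passed. In the 8 fits without 1 library each, the calls of Tnfrsf10b and Sesn1 held in 4 and 3, and the highest adjusted p-values were 0.0678 without WT 4 and 0.0922 without WT 1. The calls of Sesn2, Cdkn1a and Sesn1 ended with the library code as a term (adjusted p = 0.0583, 0.0619 and 0.217). Medians and camera adjusted p-values were 0.15 and 0.0808 for the anti-apoptotic, -0.03 and 0.539 for the pro-apoptotic and 0.12 and 0.0901 for the p53 list, beside the myeloid difference of 2.90. The anti-apoptotic list passed, upward, without KO 5 (0.0139), with limma-voom (0.0232) and with the host number as a block in DESeq2 (0.0431). The p53 list passed, upward, without WT 4 (0.0390), with limma-voom (0.0123) and by fry (0.0378). With an estimated correlation camera gave each of these lists adjusted p = 0.788 with all libraries.

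Interferon-stimulated genes split, beside the same myeloid difference of 2.90. Of 33 measured, 6 rose and 2 fell (12 and 3 adjusted over the list alone). The oligoadenylate synthetase family led the rises with Oasl2 (2.28 ± 0.30), Oas2 (2.15 ± 0.29), Oasl1 (2.31 ± 0.33) and Oas1a (0.78 ± 0.13), followed by Ifit3 (0.73 ± 0.14) and Ifi35 (0.27 ± 0.06), and reads can be shared within that family. With the myeloid covariate Oas2 turned downward (-0.44), Oasl2 was at 0.0120 and Oasl1 at 0.20, and none of the 6 passed. Slfn8, a schlafen gene on chromosome 11 from 83002125 to 83020810, fell from 40.6 ± 2.33 to 16.9 ± 1.80 CPM (-1.26 ± 0.08, edgeR adjusted p = 2.57e-05), and the RNA sensor Ifih1 fell (-0.35 ± 0.09). Among 26 genes of the interferon-gamma and GTPase list, 3 rose and 1 fell (3 and 2 adjusted over the list alone). Ciita, which switches on MHC class II genes, rose from 1.72 ± 0.574 to 15.9 ± 6.30 CPM (3.20 ± 0.32), Cd274 by 0.50 ± 0.11 and Gbp2 by 0.42 ± 0.09, and the proteasome gene Psmb9 fell (-0.23 ± 0.06). Among fits without 1 of the 8 libraries, 3, 7, 6 and 2 kept the calls of Ifih1, Cd274, Gbp2 and Psmb9, and the highest adjusted p-values were 0.112 without WT 1, 0.0522 without WT 1, 0.0632 without WT 1 and 0.0982 without KO 1. The calls of Ifit3, Ifi35, Ifih1, Cd274, Gbp2 and Psmb9 ended with the library code as a term (adjusted p = 0.0688, 0.0984, 0.0956, 0.0907, 0.125 and 0.144). The camera adjusted p-values were 0.112 at a median of 0.10 for the first list, which passed, upward, without WT 4 (0.0356), with limma-voom (0.0131) and by fry (0.0481), and 0.742 at a median of 0.00 for the second. With an estimated correlation camera gave the first list adjusted p = 0.788 with all libraries.

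Activation and stress genes rose in small numbers, with the myeloid level 2.90 log2 units apart between the same libraries. Of 27 immediate early genes of T cell receptor signalling, 5 rose and 1 fell, also adjusted over the list alone. They were Atf3 (1.59 ± 0.28), Klf4 (0.54 ± 0.11), Ier5 (0.40 ± 0.08), Dusp4 (0.39 ± 0.09) and Cd69, with Egr2 lower (-0.43 ± 0.11, edgeR adjusted p = 0.0333). With 1 library left out at a time, the calls of Dusp4 and Egr2 held in 5 and 2 of 8 fits, and the highest adjusted p-values were 0.0593 without KO 5 and 0.0963 without WT 1. The calls of Klf4, Ier5, Dusp4 and Egr2 ended with the library code as a term (adjusted p = 0.0705, 0.0976, 0.145 and 0.196). Of 24 genes of the unfolded protein response, 4 rose and 0 fell (5 and 0 adjusted over the list alone): Atf3, Ppp1r15a (0.34 ± 0.06), Sesn2 and the chaperone gene Calr (0.22 ± 0.05). camera called that list at adjusted p = 0.00859, lost at adjusted p = 0.788 with an estimated correlation, 0.0655 without KO 4, 0.146 without KO 2 and KO 4, 0.0840 with the library code as a term, 0.0520 by fry and 0.893 with the myeloid covariate. Atf3 (-0.28) and Klf4 (-0.05) turned downward with the covariate and did not pass. Of 18 heat shock genes, the cochaperones Bag3 (0.63 ± 0.09) and Dnajb4 (0.33 ± 0.06) rose and 0 fell, also adjusted over the list alone, while Hspb1 (0.41) and Hspa4l (-0.17) did not pass. The calls of Calr and Dnajb4 ended with the library code as a term (adjusted p = 0.123 and 0.0557). The camera adjusted p-values of the immediate early and heat shock lists were 0.0905 and 0.213. The immediate early list passed, upward, without WT 1 (0.0104), KO 2 (0.0126) or KO 5 (0.0496), and downward with the myeloid covariate (0.0193). With the estimated correlation of 0.350 camera gave that list adjusted p = 0.840 with all libraries.

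Metabolic and proliferation genes changed little, beside the myeloid difference of 2.90. Of 23 glycolysis genes, the lactate transporter gene Slc16a3 rose (0.82 ± 0.21, edgeR adjusted p = 0.0402) and 0 passed adjusted over the list alone, while Hk2 (0.64 ± 0.20), Gapdh (-0.29 ± 0.10) and Slc2a1 (0.44 ± 0.15) did not pass. With the myeloid covariate Slc16a3 turned downward (-0.84) and did not pass. The count of Gapdh, which has many processed copies in the genome, is uncertain where reads were shared. Hk2 passed without KO 5 (0.76, adjusted p = 0.0451). Of 38 genes of oxidative phosphorylation, Sdha fell (-0.21 ± 0.04, adjusted p = 0.00870) and 0 rose, also adjusted over the list alone, and Ndufs6 (-0.11), Cyc1 (0.08) and Ndufa4 (-0.15) did not pass. That list had a median of 0.01 and a mean of 0.00, and was ranked downward by camera (adjusted p = 0.830) and upward by fry (adjusted p = 0.957). Of 20 genes of cholesterol synthesis, Dhcr7 fell (-0.26 ± 0.06) and 0 rose, also adjusted over the list alone, with Insig1 (0.15), Srebf2 (-0.11) and Fdft1 (-0.17) not past the test, of which Insig1 passed without WT 1 (0.18, adjusted p = 0.0308). Of 23 autophagy and lysosome genes, the lysosomal membrane gene Lamp1 rose from 99.4 ± 5.07 to 151 ± 11.5 CPM (0.60 ± 0.06, adjusted p = 0.000415) and 0 fell, also adjusted over the list alone. Tfeb (-0.23), Atg9a (0.19) and Sqstm1 (0.26) did not pass, and passed without WT 4 for Tfeb (-0.27, adjusted p = 0.0441) and without KO 5 for Sqstm1 (0.33, adjusted p = 0.0479). The calls of Slc16a3 and Dhcr7 held in 3 and 5 of the 8 fits that left out 1 library, and the highest adjusted p-values were 0.111 without WT 1 and 0.0641 without KO 1. The calls of Slc16a3, Sdha and Dhcr7 ended with the library code as a term (adjusted p = 0.221, 0.0791 and 0.0919). camera gave adjusted p = 0.411 for glycolysis, 0.539 for cholesterol synthesis and 0.465 for autophagy.

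No gene of the cell cycle or histone lists passed edgeR's test, with or without adjustment over the list alone, and 0 did at an unadjusted p under 0.05, in DESeq2 or in limma-voom. Among 30 genes of S phase the median log2 fold change was -0.04, with Mcm6 at -0.13 ± 0.07, E2f1 at 0.17 ± 0.11, Pcna at 0.07 ± 0.06 and Cdt1 at 0.11 ± 0.10. Among 31 genes of G2 and M phase the median was -0.04, with Nuf2 at 0.22 ± 0.16, Aurka at -0.17 ± 0.13, Cdk1 at -0.12 ± 0.16 and Cenpf at -0.13 ± 0.18. Mki67, a proliferation marker, was at 678 ± 44.6 CPM under the wild-type label and 661 ± 156 CPM under the knock-out label (-0.04 ± 0.16, adjusted p = 0.935), and Nuf2 passed without KO 4 (0.37, adjusted p = 0.0229). The 11 histone genes had a median of -0.01, with Hist1h1e at -0.12, Hist1h4i at 0.09, Hist1h1d at -0.09 and Hist1h4d at 0.07, and reads can be shared among such near-copies. The camera adjusted p-values of the S phase, G2 and M phase and histone lists were 0.539, 0.411 and 0.830 with all libraries. The list of G2 and M phase, which camera ranked downward, passed in that direction without KO 5 (0.0299). The S phase list and the list of G2 and M phase passed in the upward direction with the myeloid covariate (0.000486 and 9.51e-06) and without KO 2 and KO 4 (0.0418 and 0.0387), so the direction of these lists is left open. These passes rest on the preset correlation of 0.01, where 0.834 and 0.935 were estimated for the lists. With the estimates camera gave adjusted p = 0.936 for each with all libraries. Histone genes took 0.00546% of counts under the wild-type label and 0.00536% under the knock-out label (exact permutation p = 0.943). The 82 ribosomal protein genes took 2.59% and 2.65% (p = 0.314 by the same exact test), and the 10 most counted genes 4.58% and 4.65% (p = 0.343 by the same exact test), with adjusted p = 0.514 for each of these shares.

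**Figure D4:**
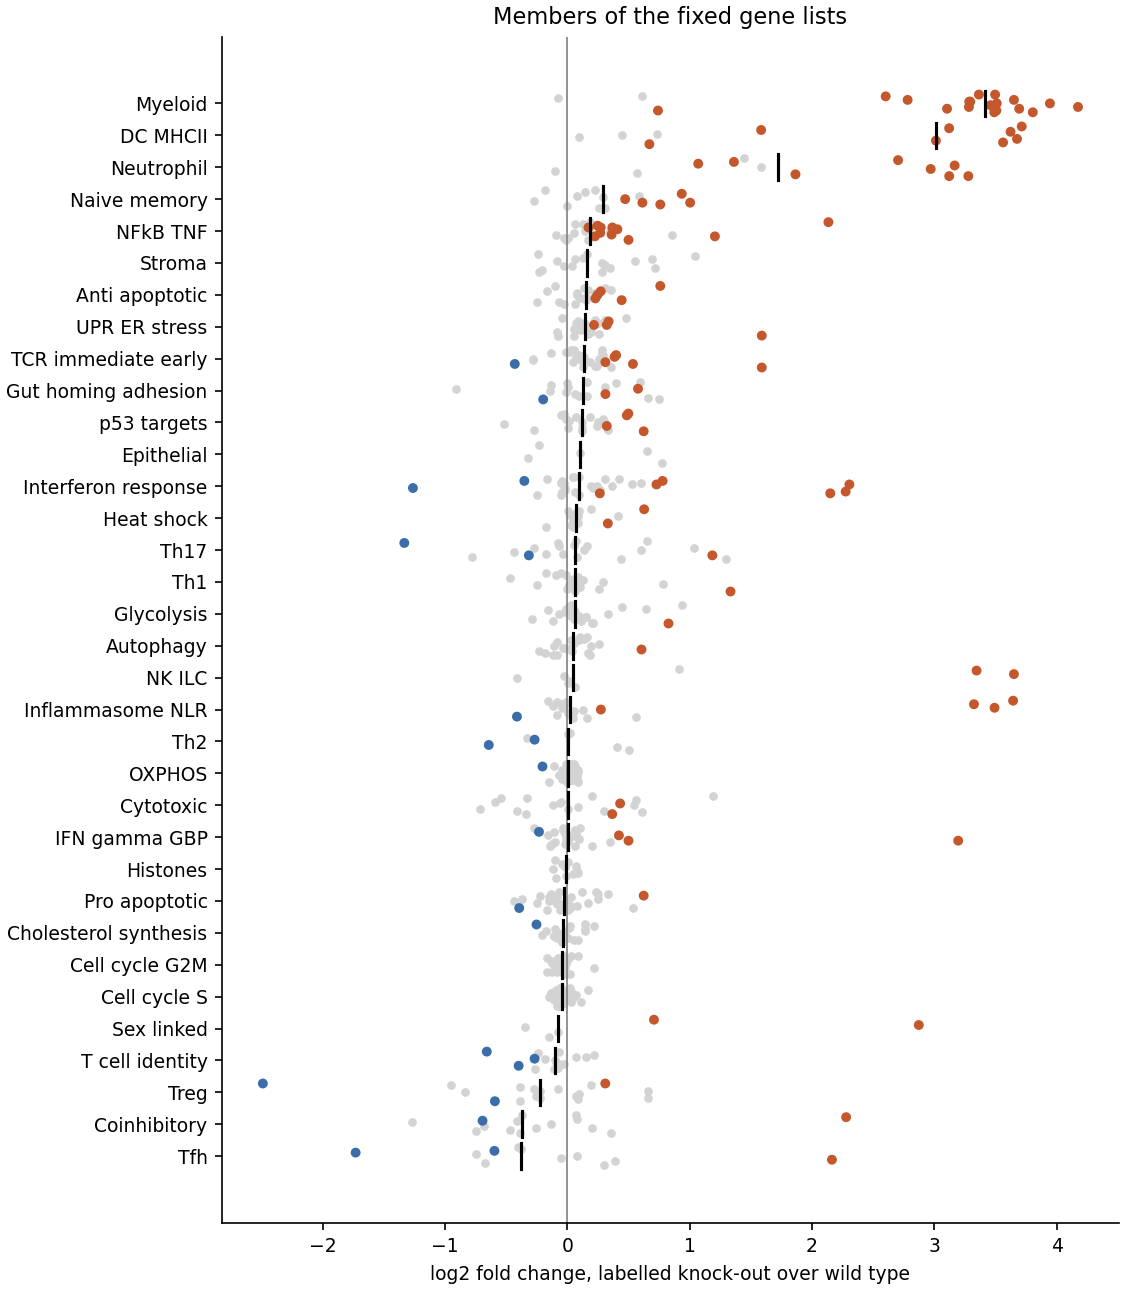
Log2 fold changes (x axis, libraries labelled knock-out over wild type) of the members of 34 of the 35 gene lists with at least 5 measured genes (the list around Nlrp6 is not drawn), with called genes in orange (higher) or blue (lower), other genes in grey and a black bar at each list's median. The myeloid and dendritic medians lie at 3.41 and 3.01, the neutrophil median at 1.72, and the lowest medians are those of the follicular helper (-0.38) and coinhibitory (-0.37) lists.

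The called genes were unevenly placed along the genome. On chromosome 11, 144 of 965 genes (14.9%) were called, an odds ratio of 1.66 against all other chromosomes (95% interval 1.36 to 2.00, two-sided Fisher's exact test adjusted over 20 chromosomes, p = 5.45e-06). On chromosome 1, 108 of 644 genes (16.8%) were called, an odds ratio of 1.89 (1.51 to 2.35, adjusted p = 1.01e-06), and no other chromosome passed. Both chromosomes had more genes that rose, 93 and 66, than that fell, 51 and 42, as did all called genes (61.8% higher). Within 1 Mb of BC018473, 15 of 38 genes tested were called, 10 higher and 5 lower. St6galnac2 (chromosome 11, 116676703 to 116695782) rose from 23.1 ± 2.63 to 337 ± 28.8 CPM and St6galnac1 (chromosome 11, 116765025 to 116775507) from 11.2 ± 3.92 to 145 ± 14.5 CPM. Without the genes of chromosome 11, 970 of the 996 calls elsewhere remained. Within 1 Mb of Nlrp6 on chromosome 7, 3 of 46 genes were called, all lower, with a median log2 fold change of -0.01. In windows of 5 Mb, tested after the result was seen, 11 of 67 genes were called at 140 to 145 Mb, around Nlrp6. At 125 to 130 Mb, with Itgad and Rgs10, 17 of 92 were called, 12 of them lower. Neither window passed (one-sided Fisher's exact test adjusted over windows, p = 0.855 and 0.316). Neighbouring calls were in excess on chromosome 7 (19 pairs, median 10 in shuffles, permutation adjusted p = 0.00629). Such an excess passed on 8 of the 20 chromosomes, so it is not particular to chromosome 7. In a wider list of 42 genes around and including Nlrp6, 2 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.830). Its median log2 fold change was -0.03 and its mean, which takes in Nlrp6 itself at 6.70, was 0.13. The list was ranked downward by camera and upward by fry.

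Among the genes of that wider list, the phosphatase gene Dusp8 rose by 0.83 ± 0.11, and Tspan32 (-0.83 ± 0.12), Pgghg (-0.44 ± 0.08) and Sigirr (-0.34 ± 0.06) fell (edgeR adjusted p at most 0.00556). Pgghg (chromosome 7, 140941391 to 140947664) is the nearest of these to Nlrp6. Among 5 genes that differ between the sexes, 2 rose and 0 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.287). Their median log2 fold change was -0.07, their mean 0.60 and their direction in camera upward. Xist, the RNA of the inactive X chromosome, rose from 4.15 ± 1.42 to 30.4 ± 9.37 CPM (2.87 ± 0.29, adjusted p = 0.000415), beside the myeloid difference of 2.90. The Y-linked Ddx3y rose from 136 ± 16.8 to 222 ± 39.6 CPM (0.71 ± 0.13, adjusted p = 0.00691), whereas the Y-linked Kdm5d (-0.15 ± 0.05) and Eif2s3y (-0.35 ± 0.11) did not pass over all genes, and Eif2s3y passed without KO 4 (-0.45, adjusted p = 0.0178).

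**Figure D5:**
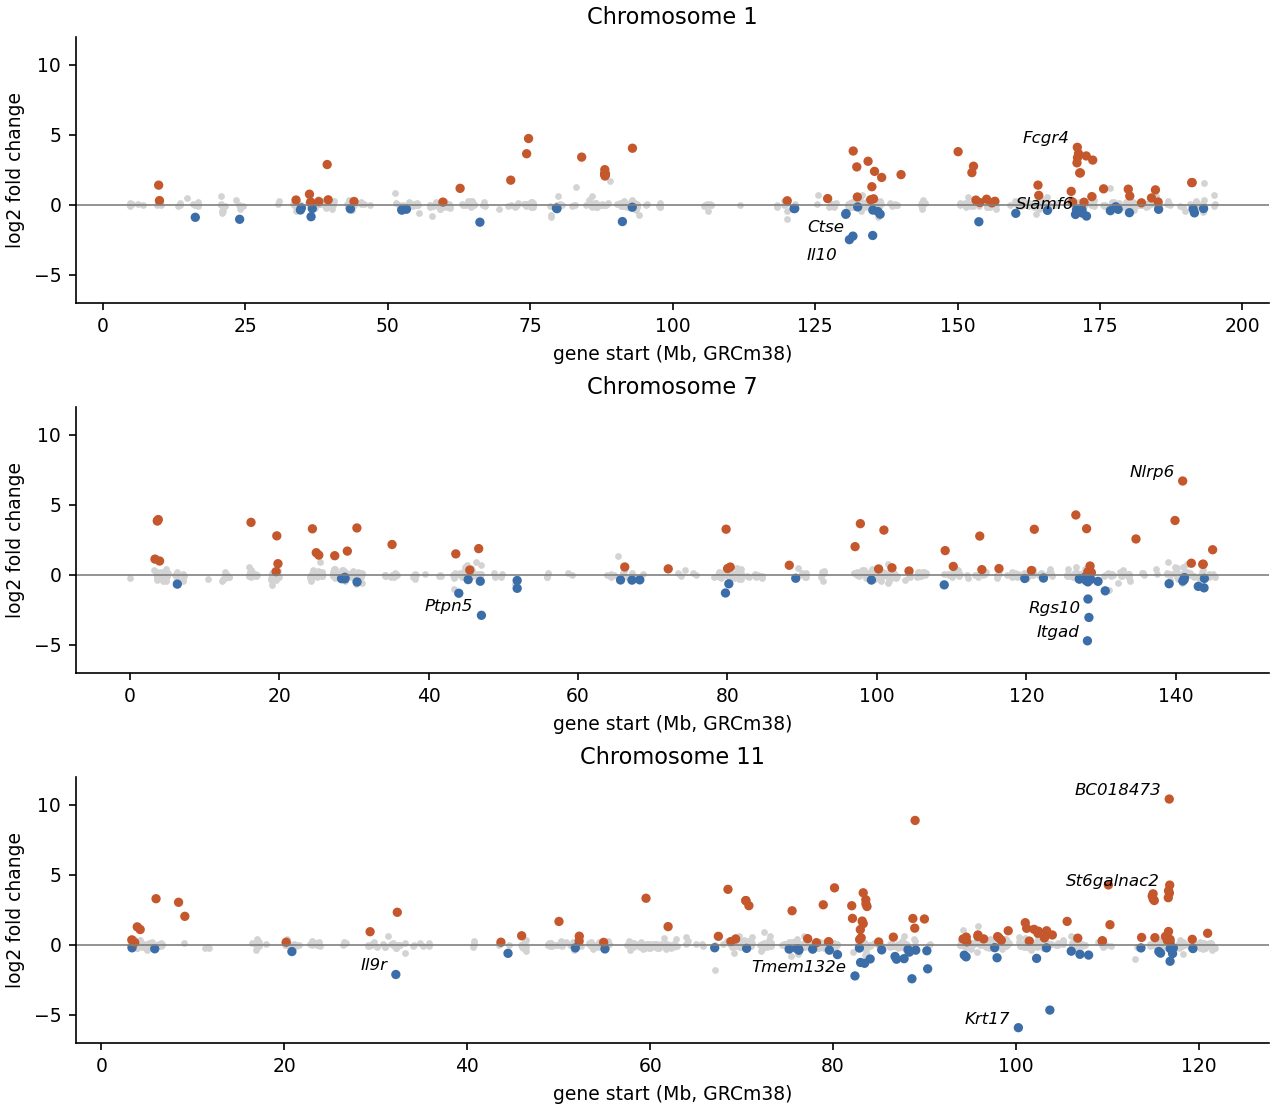
Log2 fold change (y axis, libraries labelled knock-out over wild type) of each gene against its start (x axis, Mb, GRCm38) on chromosomes 1, 7 and 11, with called genes in orange (higher) or blue (lower) and others in grey. Calls crowd on chromosome 11 (144 of 965 genes), where BC018473 lies at 10.41, and on chromosome 1 (108 of 644 genes), while Nlrp6 is the highest point on chromosome 7 at 6.70.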

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

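The tests of Nlrp6, of the share of calls on chromosome 11, also in shuffled blocks, and of neighbouring calls on the other chromosomes, the covariate fit and the comparison with epithelial and stromal lists were chosen only after the result was seen.

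Per total counts, Nlrp6 was 105-fold higher (counting interval 67.2 to 175) in the libraries labelled knock-out, against the labels. A single wrong label, or 1 swapped pair, would leave a library of one label in the range of the other, and 0 libraries labelled knock-out lay at or below the highest library labelled wild type. Reads brought by myeloid cells are argued against by size, since the log2 fold change of Nlrp6 exceeded that of Fcgr1, the highest in the myeloid list, by 2.52 (combined SE 0.59). An exchange of all group labels may give this pattern. A knock-out allele that is still transcribed may give it only if it yields far more Nlrp6 reads than the wild-type gene. These explanations cannot be told apart, because the labels give a donor genotype for 0 genes other than Nlrp6 and the counts do not separate exons. Until that is settled, each direction in the report may have to be read the other way round.

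Myeloid genes were higher in all libraries labelled knock-out. A lower share of T cells, which raises every other cell type alike, is argued against by the epithelial and stromal lists. Their higher median log2 fold change was 0.16, where the lowest quartile of the myeloid list was 3.02. That holds only as far as these lists measure epithelial and stromal cells. Only 5 of 22 epithelial genes were measured, the stromal list shares Thy1 with the T cell identity list, and the tissue is left open. Myeloid cells or their RNA in the preparation may account for the higher myeloid genes. The myeloid list's members varied together among libraries of the same label, with a median pairwise correlation of 0.857 (lowest 0.22). Lyz2 averaged 201 CPM under the knock-out label and 23.3 CPM under the wild-type label, and the labels name no sort or gate that would remove myeloid cells. Of the 20 list genes, 17 were at 1 CPM or more under the wild-type label too, 5 at 10 CPM or more, and 1 is also in another list. The myeloid level lies between the labels for 90.8% of its variance, so a fit that holds it constant leaves few called genes and cannot show which of the others differ in the T cells themselves, and an effect of the donor genotype on the myeloid cells of the hosts remains untested.

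Calls were concentrated on chromosome 11. Fisher's test takes genes as placed one by one, so calls were also shuffled over the genome in blocks of 10, 20 or 50 neighbouring genes. Chance placement is argued against, since the adjusted p over 20 chromosomes was at most 0.0107 (144 called genes on chromosome 11, median 96 in the shuffles). Genes of myeloid cells that happen to lie there stay open. The lower calls, to which such cells add no reads, had an odds ratio of 1.45 (95% interval 1.05 to 1.96). That goes against such genes as the whole cause only if myeloid RNA does not lower T cell genes by taking a share of the counts. This was not tested, and the interval also takes genes 1 by 1. In blocks the one-sided permutation p of the lower calls was 0.0291 to 0.0408 for chromosome 11 alone. Adjusted over chromosomes it was 0.435 to 0.619. Lower calls formed 7 neighbouring pairs on chromosome 11, where shuffles gave a median of 3 (one-sided permutation p = 0.0139). Segments of another strain in the donors of 1 label could put called genes side by side, and 41 neighbouring pairs were called where shuffled calls gave a median of 21 (permutation p = 0.0001, the smallest they can give). Neighbouring calls were in excess on 8 of 20 chromosomes, however, so the test does not single out chromosome 11, and shared local regulation and an effect of the donor genotype stay open, untested. Chromosome 1 had the higher odds ratio, 1.89, and was not weighed.

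Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many called genes as the labels (1140), namely the real one. The highest of the others gave 1. Chance is argued against for the number of genes at 1 in 35, the smallest share that these splits allow. Each other split mixes libraries of both labels, which widens the spread within its groups, so few calls are built into it. A cause that follows the labels would give the same counts. For gene lists, 34 of the 35 splits called as many as the 7 of the labels, with up to 22 in another split, so chance cannot be excluded for the number of lists. The split with 22 lists sets WT 1, WT 2, WT 5 and KO 5 against the rest, and called 0 genes; why that split calls so many lists was not tested.

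A single library lay far from the other 3 of its label in 28 of 398 groups examined, where chance gives about 1 in 20 groups, and 10 of the 28 were in KO 4. In KO 4 these were Il10 (40.8 CPM), Tbx21 (187 CPM), Zap70 (395 CPM), Ifi35 (57.5 CPM), Dnajb4 (93.0 CPM), Calr (983 CPM), St6galnac2 (380.4 CPM) and Itga1 (85.1 CPM), which were high, and Cenpf (31.4 CPM) and the total count (35198192), which were low. KO 2 was high for Ptpn5 (3.18 CPM) and Sdha (221 CPM) and low for Ifit3 (5.53 CPM) and Nfkbia (818 CPM). KO 5 was low for Kdm5d (40.2 CPM), and KO 1 was low for Itgb2 (953 CPM) and high for Krt18 (4.01 CPM). WT 5 was high for Il17a (55.4 CPM), Cd244 (1.25 CPM) and Cdh1 (11.8 CPM) and low for Ccl5 (1239 CPM). WT 4 was high for Casp1 (161 CPM) and Gapdh (15.5 CPM) and low for Ccr8 (48.6 CPM) and Krt18 (2.07 CPM). WT 1 was high for Cd8a (6.66 CPM) and low for Slc2a1 (77.6 CPM), and WT 2 was high for St6galnac2 (27.1 CPM).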

How the results depend on the processing

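The myeloid covariate and the fits without KO 2 and KO 4 or without chromosome 11 were chosen after seeing the data. The 1140 gene calls and their direction changed little with scaling: RLE factors gave 1144 calls, 1136 of them shared, and total library size 1214, 1101 shared, 55.6% of them higher against 61.8%. Among named genes, RLE factors ended the call of Il6ra and total library size that of Cd69, and limma-voom those of Il6ra, Klf3, Egr2, Slc16a3, S100a9 and Cd8a. limma-voom called 1384 (1100 shared) and DESeq2 1579 (1140 shared), the 1 CPM filter removed 8 genes, and dropping filterByExpr changed nothing, as it removes no gene. None of the alternatives but the myeloid covariate turned the direction of a called gene. Leave-one-out totals ranged from 804 to 1197, higher genes from 516 to 709 and lower genes from 276 to 509, and 6 to 10 lists were called. The lower genes numbered 277 without WT 1 and 276 without KO 1, and the cause was not tested. The log2 fold change of Nlrp6 lay between 6.05 and 7.08 over all fits and was called in each.

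The host number as a block gave 1020 calls (638 higher, 382 lower), of which 896 were shared. Same-numbered libraries are not shown to be paired: the correlations across genes of their deviations from the label means were -0.06, 0.18, -0.14 and 0.26, and 3 of 8 libraries correlated best with their own number. The block with RLE factors gave 1015 calls and with DESeq2 1424. With the block and TMM factors 14 of 186 named genes lost a call and 5 gained one, the T cell identity list gained a call (camera adjusted p = 0.0369) and the natural killer list lost one (0.0603). The block with RLE factors did the same (0.0362 and 0.0590). With DESeq2 the block ended 1 named call and added 19, and the T cell identity (0.0168) and anti-apoptotic (0.0431) lists gained a call. With the library code as a term, 745 genes were called, 249 of them lower (688 of the 1140 shared). Of 186 named genes, 37 lost a call in that fit. The code has 8 in KO 4 and KO 5 alone, so the label difference in that fit rests on KO 1 and KO 2. Lost calls can come from fewer libraries as well as from the code, and the fit cannot separate these. Among lost calls, some log2 fold changes were larger there, such as Il7r (0.76 to 0.84), and others smaller, such as Il6ra (1.19 to 0.58). An adjusted p below 0.1 raised the lower genes to 686, and a log2 fold change of at least 1 left 448 (380 higher, 68 lower), by construction. Without KO 2 and KO 4, 27 named genes lost and 10 gained a call with fewer libraries. Lost there, though kept with any 1 library left out, were Ccr7, Slamf6, Cd200r1, Pim1, Sesn2, Ifi35, Klf4, Dnajb4, Calr and Pycard. That fit without KO 2 and KO 4 called 826 genes (718 shared) and 12 lists. limma-voom also called 12 lists, and the cause was not tested for either. camera with an estimated correlation called 0 of 35 lists, where the preset correlation called 7, fry called 9 and 4 had an unadjusted p under 0.05 with the estimated correlation.

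With the myeloid level as a covariate 7 genes were called, 5 higher and 2 lower, because the level nearly follows the labels. The median log2 fold change of the higher genes went from 1.18 to 0.28 (median SE 0.214 to 0.462) and that of the lower genes from -0.44 to -0.47 (median SE 0.0846 to 0.281). Of the 1140 log2 fold changes 202 changed sign, 190 of them among higher genes. The 17 called genes among those named that changed sign were Fcgr1 (-0.20, itself a member of the myeloid list), Il6ra (-1.61), Cebpa (-0.53), Ccr7 (-0.25), Klf3 (-0.30), Mefv (-0.23), Cdkn1a (-0.19), Sesn1 (-0.38), Oas2 (-0.44), Cd83 (-1.38), Ier3 (-0.74), Atf3 (-0.28), Klf4 (-0.0514), Slc16a3 (-0.84), S100a9 (-0.19), Tyrobp (-0.27) and Cxcl2 (-0.0326). A further 20 named genes that were not called changed sign too, such as Il17a (-1.68), Areg (-1.43) and Il2 (-1.01), and none of the 37 passed in that fit. In that fit the S phase list (0.000486) and the list of G2 and M phase (9.51e-06) passed camera upward and the immediate early list downward (0.0193), against their directions without the covariate. The cell cycle lists did the same without KO 2 and KO 4 (0.0418 and 0.0387). All of these passes rest on the preset correlation. The natural killer list turned downward with the covariate (camera adjusted p = 0.903, where its alternatives ranged from 0.00566 to 0.903). Marker levels taken as medians stayed on the same side of the adjusted threshold as sums; with 1 library left out or signs flipped within host numbers, the exact tests are too small to pass it. At this depth, the simulated recovery of 73.1% of 1.5-fold changes leaves smaller changes open.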

Other observations

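The tests of 5 Mb windows and the covariate fit were chosen after the result was seen.

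Called genes were grouped in some windows of the genome. Of 371 windows of 5 Mb with at least 10 genes tested, 6 passed a one-sided Fisher's exact test adjusted over windows, where 10.03% of all placed genes were called. On chromosome 11 they were 80 to 85 Mb (19 of 56 genes called, 13 higher), 85 to 90 Mb (13 of 43, 8 lower), 110 to 115 Mb (7 of 14) and 115 to 120 Mb (21 of 86, 14 higher), the last of which holds BC018473, St6galnac1, St6galnac2 and Mxra7. The window at 170 to 175 Mb of chromosome 1, which holds Fcgr3, Fcgr4, Fcer1g, Slamf6 and Cd244, had 16 of 50 called, and that at 60 to 65 Mb of chromosome 5 had 7 of 10, all higher. The window at 130 to 135 Mb of chromosome 1, with Il10 and Ctse, had 11 of 42 called and did not pass (adjusted p = 0.120).

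The 7 genes that stayed called with the myeloid level held constant were Nlrp6, BC018473, St6galnac2, the kinase gene Camk2b and the long non-coding RNA AA465934, which were higher in the libraries labelled knock-out, and Ctse and Rgs10, which were lower. In that fit edgeR's log2 fold changes were 6.05 ± 0.74 for Nlrp6, 10.12 ± 0.40 for BC018473, 3.60 ± 0.26 for St6galnac2, 3.34 ± 0.29 for Camk2b and 3.74 ± 0.46 for AA465934. They were -2.12 ± 0.26 for Ctse and -3.63 ± 0.36 for Rgs10. BC018473, St6galnac2, Camk2b and AA465934 lie on chromosome 11. Xist, at 2.87 ± 0.29 without the covariate, was at 0.48 ± 0.44 with it, and Il10, at -2.49 ± 0.53 without it, was at -5.97 ± 1.24 with it and did not pass.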
